A study of Homo sapiens with 26 samples.

How the data were processed

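RNA of negatively selected CLL cells was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per donor and condition, after 24 h with 2 uM LMP-420 or medium alone. The deposited values are log2 expression values made with RMA, per the submitters' processing notes, a method that corrects the background, normalizes quantiles between arrays and summarises probes into probe sets. Its version is not given in the sources used here. Quantile normalization forces every array to one distribution, so a change in the total RNA output of a cell cannot be seen in these values. The deposited log2 values were used as they stand, and 0 value columns were left unused.

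The table held 54675 probe sets, 62 of them control probe sets. Names came from the platform annotation: 41091 probe sets carried 1 gene symbol, 1801 several and 11721 none, and 41037 of those with 1 symbol matched RefSeq through the Entrez identifier, which changed 0 symbols. Probe sets with several symbols or none were left out of the gene tests. Each of 19775 genes was represented by its probe set with the highest mean, and the 13868 genes whose mean reached the 40th percentile of all non-control probe sets, 4.69 on the log2 scale, were tested. Genes of the lists without a single-symbol probe set were not analysed here.

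Groups came from the treatment label and pairs from the donor code shared by titles of 1 control and 1 treated sample. The pairing was checked: deviations from the group means correlated between the arrays of a donor at 0.746 to 0.929, and 13 of 13 control arrays were closest to the treated array of their own donor. No array appeared to be deposited more than once, since arrays of a donor correlated at 0.981 to 0.995 across genes and arrays of different donors at most at 0.977.

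Treated and control arrays were compared with limma 3.58.1 in R 4.3.3, with the donor as a fixed block, moderated variances, two-sided tests and Benjamini-Hochberg adjusted p under 0.05 over all genes tested. A second count required a change of at least 1.5-fold. Gene lists, 36 in number, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. RNA quality was compared by an exact test over all swaps within donors. The procedure was tested on simulated data for the comparison of LMP-420 with control over 13868 genes. It called 72% of genes changed 1.2-fold, 96% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, with 9 calls among unchanged genes. The simulated noise was independent between genes and each change was the same in every donor. Real genes were correlated and donors differed, so these rates may not hold for the real data.

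The text names genes by a rule also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes that moved the same way in at least 11 of 13 donors, and from each list up to 3 called members with the largest change or, where none was called, the member with the smallest p. It always takes TNF, MCL1, BCL2, CDKN1A, MYC and ADA, and leaves out sex-linked markers, immunoglobulin and HLA genes. HBB is named outside this rule and was chosen after its values were seen.

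The alternatives tried were fits without the block and with a random block, no filter and a filter at the 60th percentile, the mean of all probe sets, leaving out probe sets shared between genes or transcripts, a second quantile normalization, centring on the array median, trended and robust variances, array weights, RNA quality as a covariate, leaving out each donor, a paired t-test, a Wilcoxon test, and probe sets in place of genes. Leaving out D1, D2 and D3 together and scaling to the poly-A control transcripts were added after seeing the data, as were limma fits of 100 of the 286 sets of 3 donors.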

Results

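Expression was measured in chronic lymphocytic leukaemia (CLL) cells, the slowly accumulating mature B cells of this blood cancer, after incubation with LMP-420, which the series title describes as a purine nucleoside analogue. Cells of 13 patients had been enriched by negative selection and were kept for 24 h in medium alone or with 2 uM of the compound. Each donor gave 1 control and 1 treated array, 26 arrays in all, and replicate numbers 1 to 13 in both groups name the same donors, written D1 to D13. The values were log2 expression values with array medians between 5.21 and 5.31, and the number of arrays limits their precision. The comparison asked which genes differed between treated and untreated cells of the same donor.

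LMP-420 changed 2090 of 13868 genes tested, 952 of them higher and 1138 lower in treated cells. DUSP4, a phosphatase that inactivates MAP kinases, rose 8.31-fold, and the nuclear receptor NR4A3 rose 3.70-fold, each in 13 of 13 donors. The largest falls were those of EGR3 and EGR1, transcription factors induced by B cell receptor signals, which were 7.15-fold and 6.21-fold lower, and of TNFRSF17, the receptor for B cell survival factors known as BCMA, which was 4.62-fold lower. The treated mean of TNFRSF17, 4.14, lay below the filter at 4.69, so the size of its fall is uncertain. That of EGR3, 5.00, lay close above the filter, so the size of its fall is uncertain too. Donors differed: the log2 change of TNFRSF17 ran from -4.78 in D13 to -0.15 in D3, and that of EGR1 from -5.74 in D7 to 0.28 in D2. CD79B, a signalling chain of the B cell receptor, fell in 13 of 13 donors. The changes were mostly small: 246 genes changed at least 1.5-fold, 135 upward and 111 downward, and the called genes that moved the same way in all donors numbered 290.

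The test was limma with the donor as a block and Benjamini-Hochberg adjustment at 0.05. At an unadjusted p under 0.05, 3795 genes passed. Without the replicate block limma called 0 genes, with 648 at an unadjusted p under 0.05, while a paired t-test and an exact Wilcoxon signed-rank test on the within-donor differences called 1875 and 1816. Scaling each array to its bacterial poly-A control transcripts would move the median change of all genes to 0.27 on the log2 scale and give 7383 genes higher and 147 lower, so every change below is relative to the bulk of genes on the array.

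Among the 10 largest rises, DUSP4 went from 5.87 ± 1.88 in control arrays to 8.93 ± 1.34 in treated arrays (SD, n = 13), a log2 change of 3.06 with a standard error of 0.32 and a limma adjusted p of 5.75e-05. FOSL2, an AP-1 transcription factor, rose by 2.26 (limma adjusted p = 0.00078) and NR4A3 by 1.89 (limma adjusted p = 3.5e-05). The log2 rises of LRRC32, RGS1, SLAMF7, ZNF331, DUOX2, CDK5R1 and CREM lay between 1.53 for CREM and 1.79 for LRRC32. RGS1 limits G protein signalling, SLAMF7 is a surface receptor of lymphoid cells, and CREM encodes a cAMP-responsive transcription factor. All of these rose in 13 of 13 donors except SLAMF7 and DUOX2, which were higher in 11. The control mean of DUOX2, 4.88, lay close to the filter, so the size of its rise is uncertain.

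Among the 10 largest falls, EGR3 went from 7.84 ± 2.03 to 5.00 ± 1.87 (SD, n = 13), a log2 change of -2.84 with a standard error of 0.50 and a limma adjusted p of 0.00134. EGR1 changed by -2.64 and TNFRSF17 by -2.21. VPREB3, CNTNAP2, TLR7, PNOC, PIGR, AIM2 and PTPN6 changed by between -1.46 for VPREB3 and -1.17 for PTPN6. TLR7 is a sensor of single-stranded RNA, AIM2 a sensor of cytosolic DNA, and PTPN6 the phosphatase SHP-1. EGR3, TNFRSF17, CNTNAP2 and PTPN6 were lower in 13 of 13 donors and the other genes of this set in 11 or 12. With probe sets shared between genes or transcripts left out, PIGR was represented by another probe set, changed by -0.10 and no longer passed the test (limma adjusted p = 0.541).

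**Figure D1:**
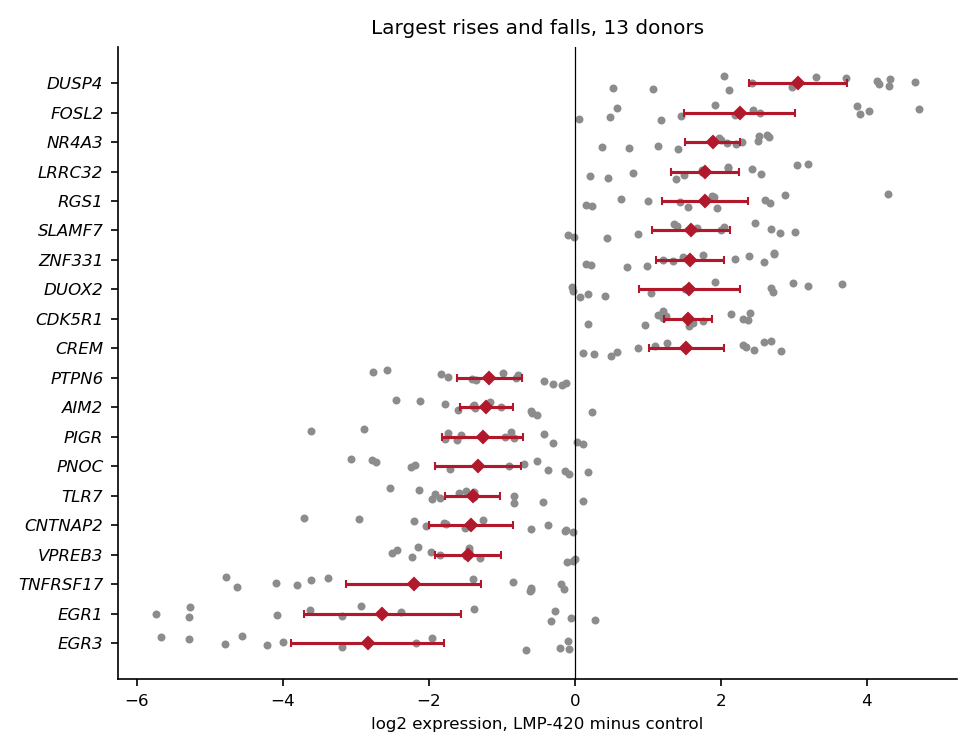
The horizontal axis gives log2 expression with LMP-420 minus control for the 10 largest rises and the 10 largest falls, with 1 grey point per donor and a red diamond with its 95% confidence interval for the limma estimate. DUSP4 at 3.06 and EGR3 at -2.84 stand at the ends. DUSP4 was higher in every donor, by 0.52 at the least, while the smallest EGR3 changes were -0.08 and -0.09.

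Over all 13868 genes tested 952 rose and 1138 fell, and the counts of each list are to be read against that share. Counts near it, as for DNA repair, pro-apoptotic and integrated stress response genes below, say nothing about the list. The share was higher among well expressed genes: the 10160 genes past the filter at the 60th percentile held 1956 of the 2090 calls. A list of well expressed genes can therefore exceed the share through its level alone, which was not tested. Of 15 tested markers of B cells and CLL cells, 10 fell, 0 rose and 5 were not called. Of 22 signalling components of the B cell receptor 9 fell, 1 rose and 12 were not called. Of 24 genes of the surface and homing list 12 fell, 2 rose and 10 were not called. These 3 lists passed camera of limma at its preset correlation (adjusted p = 5.56e-07, 2.11e-05 and 0.00111), and none of them did with an estimated correlation (adjusted p = 0.115, 0.115 and 0.186). CD79B changed by -0.95 (limma adjusted p = 9.55e-05), PTPN6 by -1.17 and BANK1, an adaptor of the receptor, by -0.58. FMOD, a proteoglycan known to be expressed by CLL cells, changed by -0.94, and FCRLA by -0.82. The genes of the surface and homing list that fell include TNFRSF17, TLR7 and FCRL2, the last with -0.89. The donor means of the marker list and of the surface list were below those of the other genes in 13 of 13 donors. CD79A, CD79B and CD22 stand in both of the first lists, and CD200 in the marker and surface lists, so these lists are not independent. Adjusted over the list alone, 13 markers, 12 signalling components and 15 genes of the surface list were lower. Scaling to the poly-A controls adds the same shift to every gene, so the medians of these lists become -0.06 for markers, 0.10 for signalling and 0.02 for the surface list.

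Of 20 tested genes on the list for cAMP and adenosine signalling, 9 rose, 1 fell and 10 were not called. Camera of limma gave this list adjusted p = 2.11e-05 at the preset correlation and adjusted p = 0.136 with an estimated correlation, and its mean was above that of the other genes in 13 of 13 donors. FOSL2, NR4A3 and CREM led it. Of 22 genes induced early after B cell receptor ligation, 9 rose and 4 fell. NR4A1, NR4A2, NR4A3, DUSP1 and RGS2 stand in this list and in the cAMP list, so these lists are not independent. DUSP4 rose while EGR1 and EGR3 fell, so members of the early response list went both ways. Camera of limma gave the early response list adjusted p = 0.000328, against adjusted p = 0.115 with an estimated correlation. Adjusted over the list alone, 11 cAMP genes were higher and 3 lower, and 11 early response genes were higher and 5 lower. Without D1, D2 and D3 the early response list no longer passed camera (adjusted p = 0.052).

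A further 7 lists passed camera of limma upward at the preset correlation. With an estimated correlation their adjusted p = 0.062 for autophagy and lysosome, 0.0528 for glycolysis and hypoxia, 0.285 for the unfolded protein response, 0.357 for heat shock, 0.285 for cholesterol synthesis, 0.188 for metallothioneins and 0.115 for histones. Other stress and metabolic lists did not pass at the preset correlation: oxidative stress (adjusted p = 0.263), integrated stress response (0.367), oxidative phosphorylation (0.811) and purine metabolism (0.980). For autophagy and lysosome genes 9 of 22 rose and 1 fell: GABARAPL1, a protein of autophagosome membranes, rose by 1.44 on the log2 scale and WIPI1 by 0.37, whereas TFEB, a transcription factor of lysosomal genes, changed by -0.90 and was lower in 13 of 13 donors. For glycolysis and hypoxia genes 7 of 26 rose and 1 fell, with ADM at 1.17, PFKFB3 at 0.69 and NDRG1 at 0.69. For the unfolded protein response 7 of 21 rose and 0 fell, with XBP1 at 0.43, HYOU1 at 0.31 and EDEM1 at 0.24. Over the mean of its probe sets XBP1 was at 0.22 and not called (limma adjusted p = 0.0991). Of 13 heat shock genes 4 rose and 2 fell: the mitochondrial chaperones HSPE1 and HSPD1 were higher by 0.76 and 0.73, and HSPB1 changed by -0.54. Cholesterol synthesis genes rose in 4 of 14 cases, led by SC5D at 0.99, IDI1 at 0.54 and DHCR7 at 0.40. IDI1 is uncertain, since 2 of its 4 probe sets went the other way. Metallothioneins and zinc genes rose in 4 of 7 cases (MT2A by 0.36, MT1H by 0.25 and MT1F by 0.24), and their near-identical sequences can share probes. MT1F was not called with a random block (limma adjusted p = 0.0568) or with no filter (limma adjusted p = 0.0588). Replication-dependent histone genes rose in 5 of 7 cases, with H1-2 at 0.54, H2BC21 at 0.43 and H2BC9 at 0.38.

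Adjusted over the list alone, the counts higher and lower were 9 and 1 for autophagy, 9 and 1 for glycolysis, 8 and 0 for the unfolded protein response, 7 and 3 for heat shock, 4 and 0 for cholesterol synthesis, 7 and 0 for metallothioneins and 5 and 0 for histones. With shared probe sets left out, camera adjusted p was 0.0736 for heat shock, 0.262 for glycolysis and 0.092 for autophagy, and with poly-A scaling it was 0.057 for the unfolded protein response. Of the 36 lists 12 passed at the preset correlation and 0 with an estimated one. With fry, which asks whether the genes of a list move one way and does not compare them with other genes, 17 passed: these 12, and replication, interferon response, antigen presentation, cytokines and ribosomal proteins. The number passing at the preset correlation was reached or exceeded in 9 of 100 labellings, the real one included, in which arrays were swapped within donors. The counts of called members in single lists were not tested with these labellings.

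**Figure D2:**
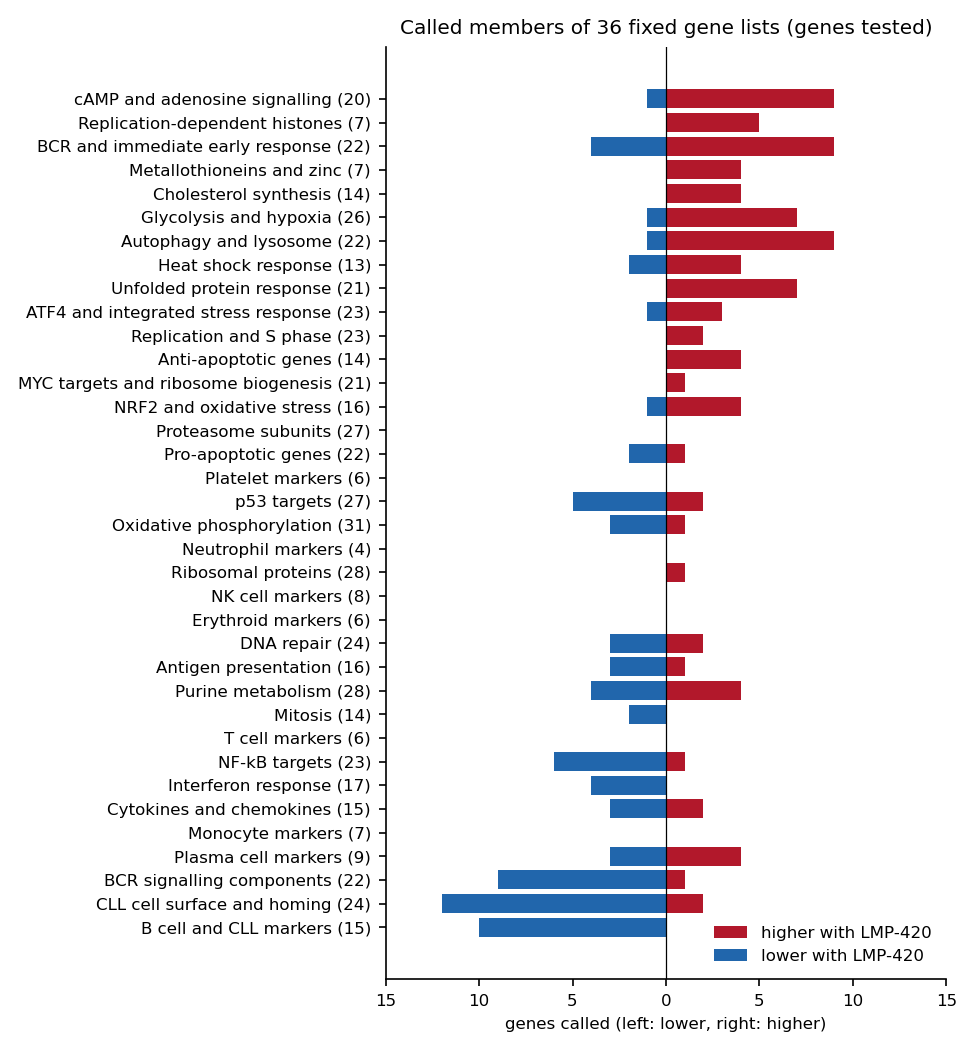
The horizontal axis counts the genes of each of 36 lists that limma called, higher with LMP-420 to the right in red and lower to the left in blue, with the number of genes tested in parentheses and lists ordered by their mean log2 change. B cell and CLL markers show 10 lower and 0 higher, and the cAMP list shows 9 higher and 1 lower.

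CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.84 in 13 of 13 donors, but of 27 tested p53 targets 2 rose and 5 fell; PTPRE changed by 0.78 and POLH by -0.43, which was -0.25 and not called with shared probe sets left out (limma adjusted p = 0.134). Of 22 pro-apoptotic genes 1 rose and 2 fell: BCL2L11, which encodes the BH3-only protein BIM, rose by 0.56 in 13 of 13 donors, TNFSF10, which encodes TRAIL, changed by -0.76 and BMF by -0.35, which lost its call with poly-A scaling (-0.08, limma adjusted p = 0.543). Of 14 anti-apoptotic genes 4 rose and 0 fell, among them PIM3 at 0.33, BAG1 at 0.24 and PIM2 at 0.24. MCL1 (-0.15, limma adjusted p = 0.115) and BCL2 (-0.13, limma adjusted p = 0.0592) were not called, the latter passing under 4 other settings. PIM2 lost its call with a random block (limma adjusted p = 0.0561). Adjusted over the list alone, 4 p53 targets were higher and 8 lower, 1 pro-apoptotic gene was higher and 2 lower, and 4 anti-apoptotic genes were higher and 1 lower. None of these lists passed camera of limma at the preset correlation (adjusted p = 0.331, 0.263 and 0.367, in this order).

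Of 23 NF-kB targets 6 fell and 1 rose. NFKBIA, NFKBIE and TNFAIP3, which encode feedback inhibitors of the pathway, changed by -0.67, -0.58 and -0.46, the last losing its call with poly-A scaling (-0.19, limma adjusted p = 0.135). TNF had a log2 change of -0.10 and was not called (95% confidence interval -0.24 to 0.03, limma adjusted p = 0.327), although it was lower in 11 of 13 donors. Without D9, 1 of 13 fits leaving out 1 donor, it was at -0.16 and called (limma adjusted p = 0.0400). Of 15 cytokine and chemokine genes 3 fell and 2 rose. LTB changed by -0.68, with 1 of its 2 probe sets in the other direction. CCL4 changed by -0.73, a call that was lost in 9 of the 13 fits that left out 1 donor (limma adjusted p = 0.0552 to 0.0839). It was also lost with no filter, a second quantile normalization, median centring, trended and robust variances, array weights, and without D1, D2 and D3 (limma adjusted p = 0.0515 to 0.124). Of 17 interferon response genes 4 fell and 0 rose, with OAS1 at -0.75, XAF1 at -0.33 and OAS2 at -0.26. OAS2 was not called with the replicate block as a random effect (limma adjusted p = 0.235) or without D1, D2 and D3 (limma adjusted p = 0.0516), and with poly-A scaling neither XAF1 (-0.05, limma adjusted p = 0.683) nor OAS2 (0.018, limma adjusted p = 0.888) was. In antigen presentation 3 of 16 genes fell and 1 rose: CD40 changed by -0.24, CIITA by -0.23 and the protease gene LGMN by 0.64. With poly-A scaling CD40 (0.035) and CIITA (0.049) changed sign and were not called (limma adjusted p = 0.782 and 0.692), and LGMN was not called with a random block (limma adjusted p = 0.0645). Adjusted over the list alone, the counts higher and lower were 2 and 7 for NF-kB targets, 2 and 4 for cytokines, 1 and 5 for interferon response and 1 and 4 for antigen presentation. These lists did not pass camera of limma (adjusted p = 0.184, 0.348, 0.111 and 0.214). The NF-kB list passed it without D1 (adjusted p = 0.0477) and without D1, D2 and D3 (adjusted p = 0.0305).

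Of 28 purine metabolism genes 4 rose and 4 fell. ADA, which encodes adenosine deaminase, changed by -0.44 and was lower in 13 of 13 donors. DCK, whose product phosphorylates deoxynucleosides and nucleoside drugs, changed by -0.32, and IMPDH2, an enzyme of guanine nucleotide synthesis, rose by 0.19. Scaled to the poly-A controls, ADA (-0.17, limma adjusted p = 0.182) and DCK (-0.04, 0.747) were not called, and with the replicate block as a random effect IMPDH2 was not (0.107). In the list for the integrated stress response 3 of 23 genes rose and 1 fell, with DDIT4 at 1.00, SLC7A5 at 0.63 and SLC3A2 at 0.51. Of 16 oxidative stress genes 4 rose and 1 fell, with SQSTM1 at 0.32, TXN at 0.30 and CAT at -0.27. With shared probe sets left out SQSTM1 was at 0.14 and not called (limma adjusted p = 0.534). Of 9 plasma cell markers 4 rose and 3 fell: IRF4 rose by 0.70 and MZB1 by 0.44, against TNFRSF17 at -2.21. MZB1 was not called with a random block (limma adjusted p = 0.0511). Adjusted over the list alone, the counts higher and lower were 4 and 5 for purine metabolism, 3 and 1 for the integrated stress response, 4 and 2 for oxidative stress and 5 and 3 for plasma cell markers. In several lists the median and mean differed in sign: 0.15 and -0.22 for plasma cell markers, 0.01 and -0.03 for purine metabolism, -0.01 and 0.08 for the integrated stress response, and 0.02 and -0.05 for mitosis. Camera of limma passed none of these lists and took the direction of the mean except for plasma cell markers.

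Of 23 replication genes 2 rose, MCM6 by 0.49 and MCM4 by 0.23. Of 14 mitosis genes 2 fell, BUB1B with -0.63 and TOP2A with -0.44. TOP2A was not called with a random block (limma adjusted p = 0.109) or with poly-A scaling (-0.17, limma adjusted p = 0.184). MYC was not called (log2 change -0.18, 95% confidence interval -0.67 to 0.30, limma adjusted p = 0.677). Its donors went both ways, from -1.98 in D12 to 1.02 in D4, so the mean does not describe single donors. Among 21 MYC and ribosome biogenesis genes 1 rose, NOP58 by 0.66. Of 24 DNA repair genes 3 fell and 2 rose, near the share over all genes. CHEK2 was at -0.25, XPA at -0.24 and H2AX at 0.24. H2AX was at 0.07 and not called over the mean of its probe sets (limma adjusted p = 0.238). With a random block it was not called either (limma adjusted p = 0.103). With poly-A scaling CHEK2 (0.026) and XPA (0.035) changed sign and were not called (limma adjusted p = 0.839 and 0.781). Of 31 respiratory chain genes 3 fell and 1 rose, with ATP5PB at -0.19, UQCRC2 at -0.12 and ATP5F1B at 0.14. The first 2 are uncertain: with shared probe sets left out ATP5PB was at 0.022 (limma adjusted p = 0.895) and UQCRC2 was not called (limma adjusted p = 0.167), over the mean of their probe sets neither was called (limma adjusted p = 0.25 and 0.384), and UQCRC2 was not with a random block (limma adjusted p = 0.161). RPS16, at 0.09, was the only one of 28 ribosomal protein genes called, and 0 of 27 proteasome genes were called by limma, PSMC4 being nearest (log2 change 0.10, limma adjusted p = 0.0561). PSMC4 was called with the filter at the 60th percentile, the mean of its probe sets, median centring and trended variances (limma adjusted p = 0.031, 0.0362, 0.0312 and 0.0457), without D2 or D7, and with poly-A scaling. At an unadjusted p under 0.05 the proteasome genes numbered 2. Calls lost in some fits that left out 1 donor were those of RPS16 (9 of 13 fits), MT1F (8), HSPB1, TOP2A and XBP1 (6 each), LGMN (5), PIM2 (4), and MCM4, MT1H and UQCRC2 (3 each), beside CCL4.

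Over all 13 donors limma called 0 of 6 T cell, 0 of 8 NK cell, 0 of 7 monocyte, 0 of 4 neutrophil, 0 of 6 platelet and 0 of 6 erythroid markers, and at an unadjusted p under 0.05 the numbers were 1, 0, 1, 0, 0 and 1. The smallest p of each list belonged to CD3E (-0.16, limma adjusted p = 0.0745), CTSW (-0.08, 0.231), SERPINA1 (-0.17, 0.0514), MPO (-0.06, 0.704), PF4 (-0.11, 0.291) and SLC4A1 (-0.11, 0.106). Without D1, D2 and D3, CD3E was called (-0.18, limma adjusted p = 0.0239), and array weights called CD3E, SERPINA1 and SLC4A1 (limma adjusted p = 0.028, 0.0388 and 0.0457). Without D3, CD3E and SERPINA1 were called (limma adjusted p = 0.0235 and 0.0176), and without D8, SERPINA1 (limma adjusted p = 0.0354). The 3' over 5' log2 difference of the ACTB and GAPDH control probe sets, a measure of RNA degradation, was 1.09 ± 0.47 in control and 1.06 ± 0.50 in treated arrays (SD, n = 13), and the mean difference of -0.03 had p = 0.757 in a two-sided exact test over all within-donor swaps. It was higher in the treated array in 10 of 13 donors, and without D4 the mean difference was 0.034 (p = 0.551).

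Donors differed in the changes between their arrays. The SD across genes of the log2 difference ranged from 0.20 in D3 to 0.38 in D12. It holds array noise beside the response, and was 0.31 in both D2 and D8, whose correlations below differ widely. The correlation across genes of a donor's differences with the mean of the other donors, where genes are not independent replicates, ranged from 0.05 in D2 and 0.08 in D3 to 0.74 in D8, with a median of 0.62. D1, D2 and D3 stood apart from the other 10 donors on the first principal component of the control arrays (32.8% of the variance). Without them 2736 genes were called, 1220 higher and 1516 lower, and the genes changed at least 1.5-fold rose in number to 390. On these 3 donors alone limma called 0 genes, with 732 at an unadjusted p under 0.05, where chance gives 693. Of 100 sets of 3 donors fitted alone, a comparison chosen after seeing the data and with these donors included, 45 had 0 genes called and 6 had 732 or fewer at the unadjusted p, so the 0 calls alone do not set these donors apart. Genes called in the other 10 donors changed in these by a median of 0.137 of that change, 64.5% had the same sign, and the mean changes correlated across genes at 0.23. Each value was the lowest of the 100 sets, and the other sets had medians of 0.87, 95.1% and 0.73. D1, D2 and D3 also had the lowest correlations with the other donors (0.30 in D1), so this ranking follows from that and is no separate support. On the mean response of the other 12 donors, D1 shifted by 0.46, against 0.07 in D2 and D3.

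**Figure D3:**
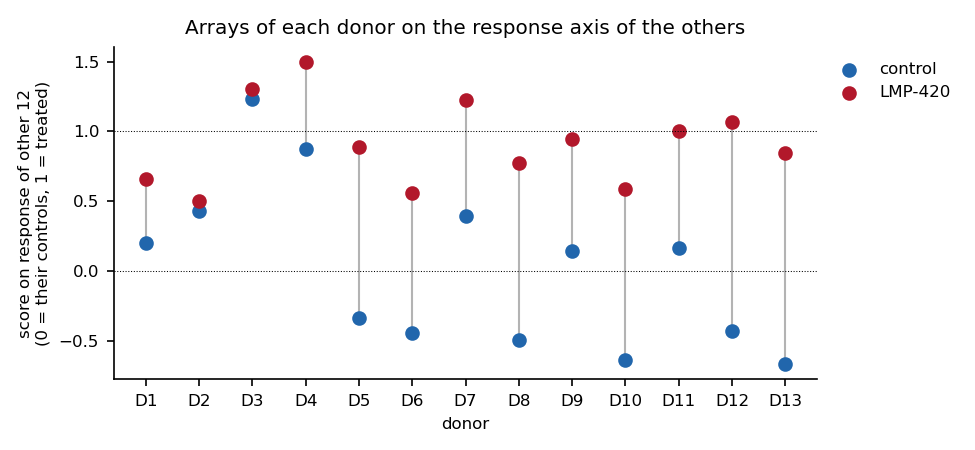
The vertical axis places the control (blue) and treated (red) array of each donor on the mean response of the other 12 donors, where 0 is the mean of their control arrays and 1 that of their treated arrays. The treated array lies above the control array in every donor, by 0.07 in D2 and D3 and by 1.51 in D13.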

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

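The tests on the 3 donors and on the poly-A controls were chosen only after those results were seen; the relabellings and the tests on RNA quality and on other blood cells were fixed earlier. In 100 labellings with arrays swapped within donors, the real one alone (1 of 100) gave as many as 2090 genes and 1 of 100 as many as 246 genes changed at least 1.5-fold. The highest other values, 1189 and 171, came from a labelling that swapped 1 donor. Chance is therefore unlikely to give counts this large, though 1 of 100 is the lowest share that 100 labellings can give. Single genes were not tested in this way. For the 12 lists passing camera, 9 of 100 labellings gave as many and the highest other gave 15, so chance cannot be excluded. With the 3' over 5' difference as a covariate the median called gene kept 1.01 of its log2 change. That share could hardly come out otherwise, since the covariate differed between the groups by only -0.03 on average. The fit therefore does not decide on RNA degradation. The mean of the 3' over 5' difference showed no shift (two-sided exact test, p = 0.757), though it was higher in the treated array in 10 of 13 donors. A shift in other blood cells cannot be told apart: the T cell, NK cell and monocyte lists had medians no farther from 0 than -0.064, which met the bound set in advance, but that bound was too lenient, since the 21 markers had control means of 4.75 to 6.56, close to the filter at 4.69. HBB, a red cell transcript far above the filter (control mean 10.51) chosen after its values were seen, changed by -0.034 (95% confidence interval -0.15 to 0.09), which goes against a shift of red cells but is 1 transcript.

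D1, D2 and D3 stood apart on the first principal component of the control arrays. A state like that after LMP-420, RNA degradation and red cell RNA cannot be told apart: each measure was higher on average in these donors, but 2, 3 and 2 control arrays of other donors, which did not stand apart, were as high as the lowest of the 3, and within the other 10 donors the measures correlated with the component at 0.24, 0.50 and 0.36, opposite to the direction needed but not beyond chance (permutation p = 0.492, 0.145 and 0.30). Of all 286 sets of 3 donors, 7 had control arrays with a mean score on the response of the other donors as high as the 0.62 of these (-0.14 in the other 10), 8 a mean 3' over 5' difference as high as their 1.55 (0.95), and 5 a mean HBB level as high as their 12.70 (9.85). A separate hybridization batch remains a candidate explanation, since 3 of 18 hybridization control probe sets separated both arrays of these donors from all others, which held for 1 of all 286 sets of 3 donors. Several of the 18 probe sets measure the same control transcript, so they do not count as independent controls. Other differences between these donors and the rest were not tested.

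Bacterial transcripts that serve as poly-A controls were lower in treated arrays by a mean of 0.27 (log2 change -0.27 ± 0.35, SD, n = 13), in 11 of 13 donors (two-sided exact test, p = 0.0181), and limma called 21 of 24 such probe sets among the 62 controls. Several of the 24 probe sets measure the same transcript, so the 21 calls are not independent. A dimmer hybridization is argued against, since the hybridization controls changed by -0.0040 on average. RNA degradation cannot be told apart: over 13 donors the change of the poly-A controls and that of the 3' over 5' difference had a Spearman rho of 0.24 (permutation p = 0.437) and a Pearson r of 0.18 (permutation p = 0.547), or 0.57 without the 2 donors farthest from the median. More messenger RNA per total RNA in treated cells, or unequal addition of the controls, may also account for the difference and was not tested.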

How the results depend on the processing

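Leaving out D1, D2 and D3 and scaling to the poly-A controls were chosen after seeing the data. Without the replicate block limma called 0 genes, 0 higher and 0 lower, and 0 at 1.5-fold in either direction; donors differed more than treatments, and the pairing by donor is by design. Array weights gave 1475 genes higher. Probe sets in place of genes gave 3792 calls, 1957 higher and 1835 lower, as more features were tested. Without D1, D2 and D3, 390 genes changed at least 1.5-fold, 192 of them lower. Scaling to the poly-A controls gave 7530 genes changed, 7383 higher (98.0% against 45.6%) and 147 lower, and 451 at 1.5-fold, 415 higher and 36 lower; this follows from the shift by 0.27. With an estimated correlation camera called 0 lists. Leaving out 1 donor gave 1663 to 2452 genes changed, 750 to 1142 higher and 913 to 1310 lower, 209 to 292 at 1.5-fold (119 to 162 higher, 86 to 140 lower), 12 to 15 lists and a mean RNA quality difference of -0.074 to 0.034. The median over donors of the SD of the log2 difference (0.306) moved by less than the spread between donors under both other filters.

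Signs turned for LTB (0.048), ATP5PB (0.022) and IDI1 (-0.017) with shared probe sets left out, and with poly-A scaling for CAT (0.00012), CHEK2 (0.026), XPA (0.035), ATP5PB (0.080), UQCRC2 (0.16), OAS2 (0.018), CD40 (0.035) and CIITA (0.049). The cause was not tested for the first 3. Poly-A scaling also ended the calls of ADA, DCK, TNFAIP3 (-0.19), BMF (-0.08), XAF1 (-0.05), TOP2A (-0.17) and POLH (-0.16). With the replicate block as a random effect the calls of UQCRC2, OAS2, TOP2A, IMPDH2, PIM2, H2AX, MT1F, MZB1 and LGMN ended. Over the mean of all probe sets those of UQCRC2, ATP5PB, CIITA, H2AX and XBP1 ended. BCL2, not called in the report, passed with the filter at the 60th percentile (limma adjusted p = 0.041), with quantile normalization again (0.0354), with trended and robust variances (0.0355) and with the random block (0.0464). Of lists not passing camera, proteasome subunits passed under 9 settings, 4 of them leaving out 1 donor, replication passed under 4 and NF-kB targets under 2, 1 of them without D1, D2 and D3 (camera of limma, adjusted p = 0.0305). Interferon response passed with no filter (camera of limma, adjusted p = 0.0177) and plasma cell markers with poly-A scaling. With fry 17 lists passed. The remaining alternatives, other than those named, left the gene counts within 1.5 times; with the replicate block as a random effect 1643 genes were called, and the array signal over background limits genes near the filter.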

Other observations

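Gene families sharing the letters that open their symbols were tested after the data had been seen, and the genes in this part were chosen after their values were seen. Of 228 families with enough tested genes, 2 passed camera of limma at the preset correlation: DUSP genes, which encode dual-specificity phosphatases (5 of 20 higher, 0 lower, adjusted p = 0.031), and metallothioneins of the MT family (3 of 9 higher, 0 lower, adjusted p = 0.031). With an estimated correlation their adjusted p = 0.425 and 0.996. Beside DUSP4, DUSP10 rose by 1.40 and DUSP1 by 1.24 on the log2 scale, each in 13 of 13 donors, and DUSP16 rose by 0.88 in 11.

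Single genes also stood out, with no group that passed a test behind them. By their letters KLF2 and KLF10 belong to the KLF family and CD180 to the CD family. Neither family passed camera of limma at the preset correlation (adjusted p = 0.954 and 0.889). TLR10, a Toll-like receptor, changed by -1.07 (limma adjusted p = 0.00623) and CD180, a related receptor on B cells, by -1.07 (limma adjusted p = 0.00212), each lower in 12 of 13 donors. The zinc finger factor KLF2 was lower in 13 of 13 donors (-0.49), whereas KLF10 was higher in 12 (1.36).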
